A study of Mus musculus with 16 samples.

How the data were processed

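The series holds RNA sequencing of mouse embryos at E10.5, with 16 libraries in 8 groups of 2. Each embryo part is a Head (above the third branchial arches) or a Tail (caudal to the forelimbs), and the genotypes are wild type (WT), Fuz KO, Gpr161 KO and Fuz;Gpr161 DKO, written DKO from here on. Per the labels' protocols, RNA was extracted with a Trizol-based kit, treated with DNase and made into poly-A selected NEBNext Ultra libraries. The deposited values are raw counts per Ensembl gene, 1 table per library, with no normalization by the authors. The submitters' processing notes name FastQC, Trimmomatic, STAR 2.7.1a, Picard 2.20.4, StringTie 2.0.4, featureCounts 1.6.0 and HTSeq without stating the role of each. Which counter made the counts, and its strand setting, are not given in the sources used here. The notes name the build GRCm39, while the identifiers fit an older mouse annotation, which was therefore used for gene names, biotypes and chromosomes alone, and no coordinates are given. Of 54838 identifiers, 54809 were matched to a name and 29 were not. Raw reads were not analysed here.

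Total counts per library ran from 39062489 to 53680317, with a median of 41951619.5. Expression is given as CPM, the counts divided by the library's TMM-adjusted total on the usual scale, as mean ± SD of the 2 libraries of a group. A group with no counts is given as 0, and where a list median needs such a gene, it was also computed with the gene at a bound of 3 counts over the group. Bounds of this kind cover counting error only.

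Counts were filtered with edgeR's filterByExpr, which left 21284 genes, and fitted in 1 model over all 16 libraries with a coefficient per group, with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood F-test, robust dispersion). The fit had 8 residual degrees of freedom and a common biological coefficient of variation of 0.257. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes are printed with the standard error (SE) obtained from the F statistic. The 18 comparisons were each mutant against WT within a region, each pair of mutants within a region, the departure of the DKO from the sum of the single mutants' log2 effects (non-additivity), the difference of each mutant's effect between Tail and Head, and Head WT against Tail WT. The labels do not say whether the 2 libraries of a group came from separate embryos, nor whether Head and Tail libraries of 1 number share an embryo, so the p-values measure only the spread between these samples.

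There were 44 gene lists, written from general knowledge with 862 symbols, 16 found through another symbol and 18 not found. Lists share genes and so are not independent. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, on log CPM with a prior count of 2, and again with a correlation estimated from the libraries. A directional rotation test (fry), which does not compare a list with other genes, was an alternative. There were 774 list tests (43 lists, 18 comparisons), adjusted within a comparison, and the sex-linked list only checked the samples. The preset correlation called 314 and the estimated kept 16.

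Comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names a fixed set everywhere, among them Fuz, Gpr161, Gli1, Ptch1, Hhip and Shh. Some genes that it names are not reported here, and the counts of named genes leave them out. For each mutant against WT it adds the 8 genes risen and the 8 fallen with the largest fold change, at an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between groups, and up to 4 members of a list by adjusted p. Other comparisons take 5 risen, 5 fallen and 2 members per list. Unnamed gene models are counted and not named by the rule, and a list without a called member is shown by a gene of the first set or by its member with the largest change. Genes outside the rule are said to have been chosen after their values were seen.

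The alternatives were RLE scaling, no filter on low counts, a filter of at least 5 CPM in 2 libraries, each region fitted alone, the replicate number as a block, removal of haemoglobin and mitochondrial genes, DESeq2 1.42.0, and leaving out each library in turn. Where this left a group with 1 library, that library was assumed to vary like the other groups. A further 5 alternatives were added after the data were seen: leaving out both Fuz KO 1 libraries, leaving out both Fuz KO 1 and both DKO 1 libraries, adding sex as a term, removing the cardiomyocyte genes, and giving each mutant of a pair its own WT library.

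The pipeline was tested on simulated data with 50 genes changed at each of several sizes. For Head Gpr161 KO against WT it recovered 34% of the genes at a log2 change of 1, 56% at 2, 72% at 3 and 84% at 4, with 5 false calls by edgeR and 39 by DESeq2. The difference of the Gpr161 KO effect between regions recovered 6% at 1, 36% at 2, 66% at 3 and 62% at 4, with 7 false calls. Head non-additivity recovered 6%, 40%, 56% and 68%, with 3 false calls, and camera called 0 lists. Simulation gives no false-call rate for real, correlated genes. Figures used matplotlib 3.10.9, Python 3.11.15 and pandas 2.3.3.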

Results

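Gene expression was measured in Head and Tail parts of WT, Fuz KO, Gpr161 KO and DKO mouse embryos at E10.5, with n = 2 libraries in each of the 8 groups, to compare the genotypes by region. Fuz encodes an effector of planar cell polarity that is needed to build cilia. Gpr161 encodes a receptor of the primary cilium that holds back Hedgehog signalling. In the Head, the total counts were 43353989 and 39761331 for WT, 40795432 and 40086140 for Fuz KO, 40175538 and 41696394 for Gpr161 KO, and 42516303 and 42434144 for DKO. In the Tail they were 42206845 and 43197924 for WT, 39736123 and 40075700 for Fuz KO, 43290460 and 39062489 for Gpr161 KO, and 44767763 and 53680317 for DKO.

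Xist, the RNA that coats the inactive X chromosome, ran from 848 to 1033 CPM in the 4 WT libraries and was at most 1.18 CPM in the Fuz KO and DKO libraries, which had Y-linked transcripts. Gpr161 KO 1 was male and Gpr161 KO 2 female in both regions, so each comparison of Fuz KO or DKO with WT also set males against females. The first principal component held 37% of the variance and parted Head from Tail. The second held 14%, and Head Fuz KO 1 (-96.2), Tail Fuz KO 1 (-71.7), Head DKO 1 (-43.7) and Tail DKO 1 (-21.9) lay lowest on it. Genes of hypoxia and glycolysis, which respond to low oxygen, had a median log2 difference from the WT mean of 2.47 in Head Fuz KO 1 and 0.13 in Head Fuz KO 2, and of 2.33 in Head DKO 1 and 0.50 in Head DKO 2. The Head Gpr161 KO libraries had 1.23 and 0.53. The Tail libraries had 2.27 and 0.10 in Fuz KO, 1.03 and 0.33 in Gpr161 KO, and 1.73 and 0.30 in DKO. Across genes, Pearson's r between the 2 libraries of a group ran from 0.961 in Head Fuz KO to 0.983 in Head WT. The difference between number 1 and number 2 correlated across genes between Head and Tail with r of 0.133 in WT, 0.437 in Fuz KO, 0.196 in Gpr161 KO and 0.282 in DKO. Between groups of other genotypes r ran from -0.0787 to 0.302, with 0.302 for Head Fuz KO and Head DKO, 0.268 for Head DKO and Tail Fuz KO and 0.242 for Tail Fuz KO and Tail DKO. Values with the replicate number as a block stand beside the results between regions. Genes are not independent replicates in these correlations.

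Fuz (ENSMUSG00000011658) was measured at 6.82 and 7.84 CPM in the Head WT libraries, 0.909 and 1.67 in Fuz KO, 8.1 and 9.22 in Gpr161 KO and 1.23 and 1.89 in DKO. In the Tail it was at 5.17 and 5.35 CPM in WT, 0.877 and 1.26 in Fuz KO, 4.95 and 7.1 in Gpr161 KO and 0.808 and 1.53 in DKO. Gpr161 (ENSMUSG00000040836) was at 55 and 54 CPM in Head WT, 25.4 and 52.5 in Fuz KO, 4.21 and 4.31 in Gpr161 KO and 3.49 and 5.44 in DKO. The Tail libraries had 46.8 and 51.5 CPM of Gpr161 in WT, 24.3 and 42.7 in Fuz KO, 4.98 and 4.08 in Gpr161 KO and 2.12 and 3.29 in DKO.

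**Figure D1:**
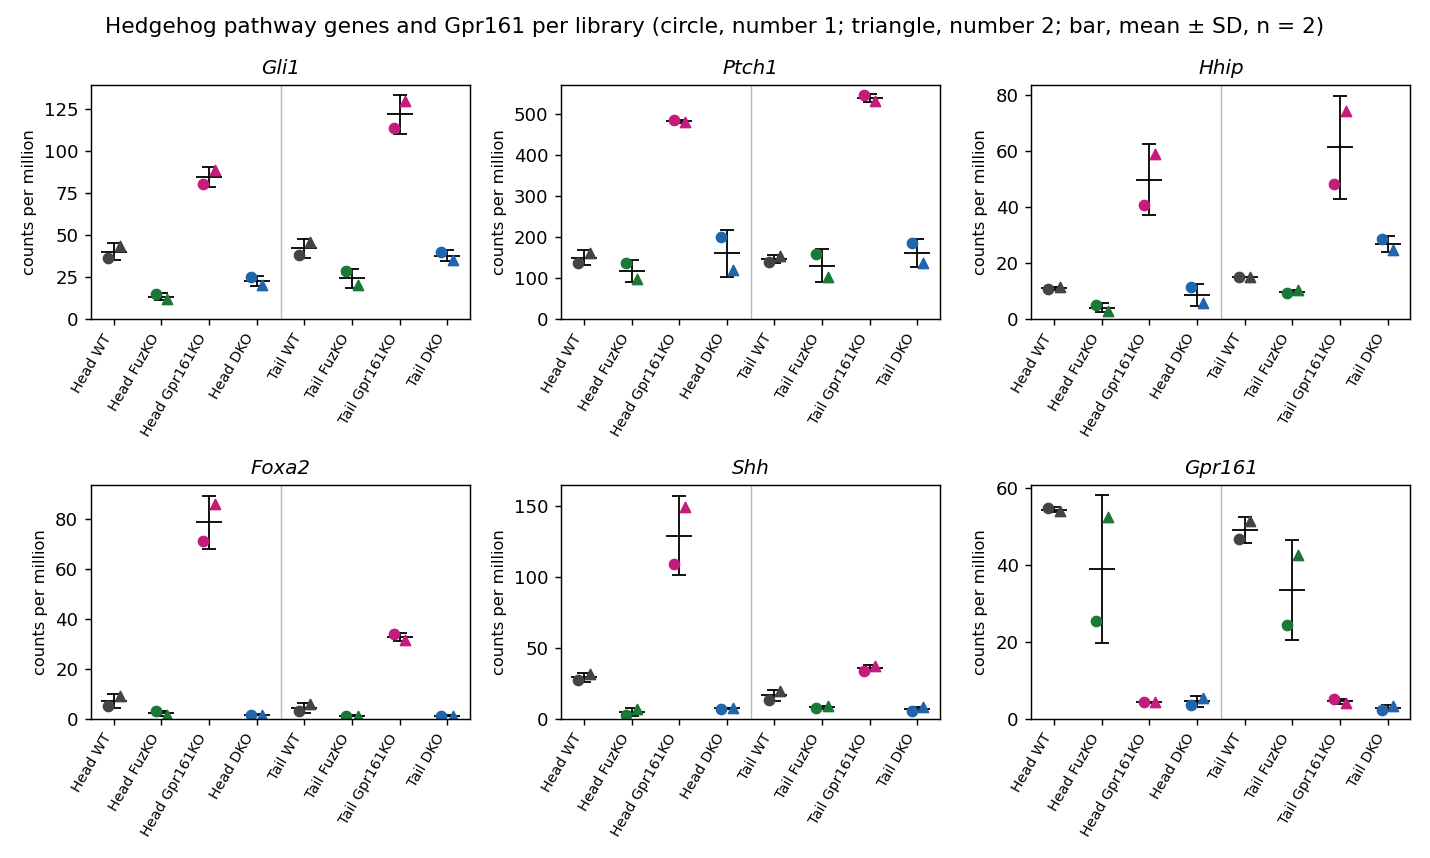
Expression of 6 genes (Gli1, Ptch1, Hhip, Foxa2, Shh and Gpr161) in CPM, with circles for libraries of number 1, triangles for number 2 and bars for the mean ± SD (n = 2) of each of the 8 groups. Ptch1 averaged 482 CPM in Head Gpr161 KO against 149 in Head WT, and 538 in Tail Gpr161 KO against 145 in Tail WT.

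The first comparison asked what loss of Fuz does to the Head. Gli1 (ENSMUSG00000025407), a transcription factor and direct target of Hedgehog signalling, was at 13.3 ± 1.88 CPM (SD, n = 2) in Fuz KO against 40.0 ± 5.2 in WT, and it fell by 1.59 on the log2 scale (SE 0.19, adjusted p = 0.00862). Shh, the ligand of the pathway in the floor plate and notochord, fell from 29.3 ± 3.09 to 4.72 ± 2.64 CPM (log2 -2.63 ± 0.33, adjusted p = 0.0123). The forkhead genes Foxl1 (log2 -3.33 ± 0.42, adjusted p = 0.0123) and Foxf2 (log2 -2.31 ± 0.34, adjusted p = 0.0473) fell with it, as did Tgfb2, a TGF-beta ligand (log2 -1.56 ± 0.22, adjusted p = 0.0278). Fuz itself fell (log2 -2.50 ± 0.39, adjusted p = 0.0493). Ptch1, the Hedgehog receptor and a target of the pathway, was at log2 -0.35 ± 0.26 (adjusted p = 0.652) and Gpr161 at log2 -0.48 ± 0.34 (adjusted p = 0.647), and neither passed. Nor did Hhip, a Hedgehog-binding inhibitor (log2 -1.48 ± 0.34, adjusted p = 0.6), which passed by DESeq2 (adjusted p = 0.00829). Among the Hedgehog target genes, 0 of 16 members rose and 3 fell, and 0 rose and 9 fell adjusted over the list alone. The list lay lower than the other genes (median log2 -1.48, camera adjusted p = 8.26e-10, adjusted p = 0.204 with an estimated correlation). Of the genes that pattern the ventral neural tube, 0 of 26 members rose and 1 fell, and 0 rose and 6 fell adjusted over the list alone, with Shh as the member that passed (median log2 -0.98, camera adjusted p = 1.76e-07, adjusted p = 0.498 with an estimated correlation). Of the forebrain and eye genes, 0 of 31 members passed by edgeR, 10 did at an unadjusted p under 0.05 and 3 by DESeq2, while 0 rose and 10 fell adjusted over the list alone (median log2 -0.65, camera adjusted p = 3.46e-08, adjusted p = 0.498 with an estimated correlation). Their median lay at -1.59 in Fuz KO 1 and -0.36 in Fuz KO 2. Of the CPLANE and intraflagellar transport genes, a list of cilium genes without Fuz, 0 of 40 members passed by edgeR, 1 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone (median log2 0.04, camera adjusted p = 0.464).

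In all, 10 genes passed in Head Fuz KO, 2 higher and 8 lower, and 1739 had an unadjusted p under 0.05. The remaining 4 were chosen after their values were seen. Gene models Gm11942 (13.7 ± 3.97 against 0.47 ± 0.0012 CPM) and Gm6969 (19.2 ± 1.03 against 0.0907 ± 0.062) rose. Nkx2-4 fell to 0 counts from 2.84 ± 0.704 CPM, and AI506816 from 78.1 ± 0.749 to 36.9 ± 0.82 (81 in DKO, 32.2 in Gpr161 KO). The hypoxia and glycolysis genes were higher (median log2 1.69, camera adjusted p = 1.92e-06, adjusted p = 0.704 with an estimated correlation), with 0 of 26 members called by edgeR. Camera's adjusted p was 0.643 without Head Fuz KO 1. In Fuz KO 1 Slc2a1, a glucose transporter, was at 1491 CPM against 186 and 185 in WT. The count was 3 without Head WT 1, 4 without Head WT 2, 5 without Head Fuz KO 1 and 2256 without Head Fuz KO 2. Of the 6 named genes called, 0 stayed called with each of these groups' libraries left out in turn (leave-one-out). The adjusted p of Gli1 was 0.0939 without Head WT 2, that of Shh 0.0833 without Head WT 1 and 0.146 without Head WT 2, and that of Fuz 0.27, 0.426 and 0.584 without Head WT 1, Head WT 2 and Head Fuz KO 1. Foxl1 had an adjusted p of 0.104 without Head WT 1 and 0.283 without Head Fuz KO 1. Foxf2 had 0.347, 0.227 and 0.944 without Head WT 1, Head WT 2 and Head Fuz KO 1. Without both Fuz KO 1 libraries Fuz (log2 -2.14 ± 0.43, adjusted p = 0.387), Foxl1 (log2 -3.23 ± 0.60, adjusted p = 0.422) and Foxf2 (log2 -2.09 ± 0.48, adjusted p = 1) kept folds within 1 SE of those above, with larger SE. Without both DKO 1 libraries as well, Fuz (log2 -2.15 ± 0.33, adjusted p = 0.0919), Shh (log2 -2.16 ± 0.29, adjusted p = 0.209), Foxl1 (log2 -3.24 ± 0.62, adjusted p = 0.728) and Foxf2 (log2 -2.10 ± 0.56, adjusted p = 1) did not pass. Sex as a term rests on Gpr161 KO 1 against Gpr161 KO 2, the only pairs of both sexes, which also differ in hypoxia and, in the Head, cardiomyocyte genes. With it 1 gene passed and 0 of the 6 named genes did. Gli1 (log2 -1.42 ± 0.26, adjusted p = 0.428), Shh (log2 -2.34 ± 0.45, adjusted p = 0.531), Fuz (log2 -2.15 ± 0.53, adjusted p = 0.967) and Tgfb2 (log2 -1.57 ± 0.32, adjusted p = 0.573) then had folds within 1 SE of those above and larger SE. Foxl1 (log2 -2.45 ± 0.43, adjusted p = 0.322) and Foxf2 (log2 -1.54 ± 0.36, adjusted p = 0.967) had smaller folds.

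Head Gpr161 KO was compared with Head WT to ask what loss of Gpr161 does there. Gli1 rose from 40.0 ± 5.2 to 84.6 ± 6.08 CPM (SD, n = 2; log2 1.08 ± 0.18, adjusted p = 0.00909), and Ptch1 from 149 ± 18.1 to 482 ± 3.86 CPM (log2 1.70 ± 0.26, adjusted p = 0.00634). Foxa2, a transcription factor of the floor plate, rose from 7.06 ± 2.63 to 78.6 ± 10.6 CPM (log2 3.48 ± 0.38, adjusted p = 0.000628), and Shh from 29.3 to 129 ± 28.2 CPM (log2 2.14 ± 0.32, adjusted p = 0.00555). Hhip (log2 2.18) and Foxl1 (log2 2.58) rose too. Among the Hedgehog targets, 8 of 16 members rose and 0 fell, and 13 rose and 0 fell adjusted over the list alone (mean log2 1.68, camera adjusted p = 8.77e-14, adjusted p = 0.0471 with an estimated correlation). The co-receptor genes Gas1 (log2 -1.92 ± 0.17) and Boc (log2 -1.63 ± 0.23) and the transcription factor gene Gli3 (log2 -0.87 ± 0.15) fell. Fuz was at log2 0.24 ± 0.36 (adjusted p = 0.855) and Gpr161 at log2 -3.68 ± 0.38 (adjusted p = 0.000608).

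Genes that pattern the neural tube changed in the same libraries. Pax3 fell from 36.8 ± 3.03 to 5.99 ± 0.386 CPM (n = 2; log2 -2.62 ± 0.17, adjusted p = 5.92e-06), and Pax7 (log2 -3.26 ± 0.35), Msx1 (log2 -1.96 ± 0.25) and the Wnt agonist Rspo1 (log2 -2.11 ± 0.23) fell. Across that list, 0 of 29 members rose and 10 fell, and 0 rose and 18 fell adjusted over the list alone (median log2 -1.88, camera adjusted p = 6.84e-18, adjusted p = 0.0471 with an estimated correlation). Pax6, which specifies eye and intermediate neural tube, fell from 73.2 ± 1.28 to 3.71 ± 1.44 CPM (log2 -4.30 ± 0.41, adjusted p = 0.000608), and the zinc finger gene Sp8 fell by 2.85 on the log2 scale (SE 0.24). Of the intermediate neural tube genes, 0 of 11 members rose and 3 fell, and 0 rose and 4 fell adjusted over the list alone (median log2 -1.31, camera adjusted p = 7.53e-07, adjusted p = 0.118 with an estimated correlation). Of the forebrain and eye genes, 0 of 31 members rose and 5 fell, and 2 rose and 10 fell adjusted over the list alone (median log2 -0.95, camera adjusted p = 1.57e-05, adjusted p = 0.252 with an estimated correlation). The ventral neural tube genes Foxa1 (log2 2.35 ± 0.35) and Ferd3l (log2 2.99 ± 0.46) rose. Of that list, 7 of 26 members rose and 2 fell, and 10 rose and 3 fell adjusted over the list alone (median log2 0.94, camera adjusted p = 0.00254, adjusted p = 0.471 with an estimated correlation). The pigment cell genes Trpm1 (log2 -6.95 ± 1.11) and Pmel (log2 -4.02 ± 0.65) and the otoconial protein gene Oc90 (log2 -5.32 ± 0.87) fell. The pseudogene Rpl34-ps1 fell by 4.54 on the log2 scale (SE 0.26).

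The canonical Wnt feedback genes Axin2 (log2 -0.72 ± 0.14), Nkd1 (log2 -0.67 ± 0.15) and Nkd2 (log2 -1.38 ± 0.23) fell. Of that list, 0 of 19 members rose and 4 fell, and 2 rose and 7 fell adjusted over the list alone (median log2 -0.57, camera adjusted p = 0.000614, adjusted p = 0.0471 with an estimated correlation). The FGF response genes Etv4 (log2 -1.09 ± 0.16) and Il17rd (log2 -0.83 ± 0.14) fell, and so did the BMP target Tbx2 (log2 -1.64 ± 0.33). The planar cell polarity genes Vangl1 (log2 1.10 ± 0.18), Celsr1 (log2 0.82 ± 0.15) and Dact1 (log2 1.01 ± 0.21) rose. In this list 3 of 24 members rose and 0 fell, and 6 rose and 0 fell adjusted over the list alone (median log2 0.24, camera adjusted p = 0.000536, adjusted p = 0.138 with an estimated correlation). The retinoic acid binding proteins Crabp1 (log2 -0.91 ± 0.20) and Crabp2 (log2 -0.93 ± 0.18) fell, as did Aldh1a1, which makes retinoic acid (log2 -3.25 ± 0.69). Among craniofacial neural crest and branchial arch genes 4 of 38 members rose and 8 fell, and 10 rose and 13 fell adjusted over the list alone (median log2 -0.36, camera adjusted p = 0.0157, adjusted p = 0.34 with an estimated correlation), with Tfap2b at log2 -1.79 ± 0.24 and Foxf2 at log2 2.03 ± 0.33. This list's adjusted p was 0.081 without Head WT 1 and 0.0511 without Head Gpr161 KO 1. The matrix genes Tnc (log2 2.60 ± 0.53), Fbn2 (log2 0.86 ± 0.12) and Sparc (log2 0.71 ± 0.14) rose. In their list 3 of 28 members rose and 0 fell, and 9 rose and 0 fell adjusted over the list alone (median log2 0.43, camera adjusted p = 2.49e-05, adjusted p = 0.198 with an estimated correlation). The cartilage collagen Col2a1 rose by log2 0.85 ± 0.19. In the sclerotome and cartilage list 2 of 22 members rose and 0 fell, and 9 rose and 1 fell adjusted over the list alone (median log2 0.92, camera adjusted p = 0.000787, adjusted p = 0.161 with an estimated correlation). The endothelial genes Plvap (log2 0.99 ± 0.16), Cdh5 (log2 0.91 ± 0.14), Sox18 (log2 0.90 ± 0.19) and Erg (log2 0.87 ± 0.19) rose. In their list 5 of 22 members rose and 0 fell, and 12 rose and 0 fell adjusted over the list alone (median log2 0.69, camera adjusted p = 2.51e-10, adjusted p = 0.118 with an estimated correlation). The list lay at 0.83 and 0.61 in the 2 libraries, in which the cardiomyocyte list lay at 6.74 and 4.46.

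The 8 risen genes that the rule names in Head Gpr161 KO belong to heart or striated muscle, and their levels differed between its 2 libraries. Myh6, the alpha heavy chain of cardiac myosin, was at 326 and 55.9 CPM in Gpr161 KO against 0.471 and 0.329 in WT (log2 8.89 ± 0.95, adjusted p = 0.00189). Myl2 (log2 9.29 ± 1.17), Myl3 (log2 9.10 ± 1.18), Myl4 (log2 7.55 ± 1.23), Mybpc3 (log2 10.21 ± 1.39), Csrp3 (log2 8.26 ± 1.23), Actn2 (log2 5.14 ± 0.66) and Ryr2 (log2 3.83 ± 0.53) rose, and all encode sarcomere or calcium handling proteins. Hspb7 and Xirp1 had 0 counts in WT and means of 23.9 ± 22.6 and 9.71 ± 7.94 CPM in Gpr161 KO. Of the list, 12 of 20 members rose and 0 fell, and 19 rose and 0 fell adjusted over the list alone (median log2 5.86, camera adjusted p = 3.6e-26, adjusted p = 0.0653 with an estimated correlation), with a median of 5.95 when genes at 0 are placed at their bound. Des, shared by heart and skeletal muscle, rose (log2 2.59 ± 0.31).

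In total 429 genes passed in Head Gpr161 KO, with 321 higher and 108 lower. Of these, 20 were unnamed gene models. The count was 42 without Head WT 1, 52 without Head WT 2, 110 without Head Gpr161 KO 1 and 189 without Head Gpr161 KO 2. Of the 70 named genes called, 14 stayed called in every leave-one-out run, among them Pax3, Pax7, Pax6, Sp8, Foxa2 and Gas1. Without Head WT 1, Head WT 2, Head Gpr161 KO 1 and Head Gpr161 KO 2 the adjusted p of Gli1 was 0.169, 0.0733, 0.0509 and 0.0786, and that of Ptch1 without the first 3 was 0.122, 0.0764 and 0.052. Without Head WT 1 and Head WT 2 it was 0.109 and 0.0957 for Hhip, 0.106 and 0.0799 for Shh, 0.056 and 0.103 for Foxl1 and 0.106 and 0.144 for Foxf2, and 0.0716 for Foxf2 without Head Gpr161 KO 2. With sex as a term 49 of the 70 named genes passed.

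**Figure D2:**
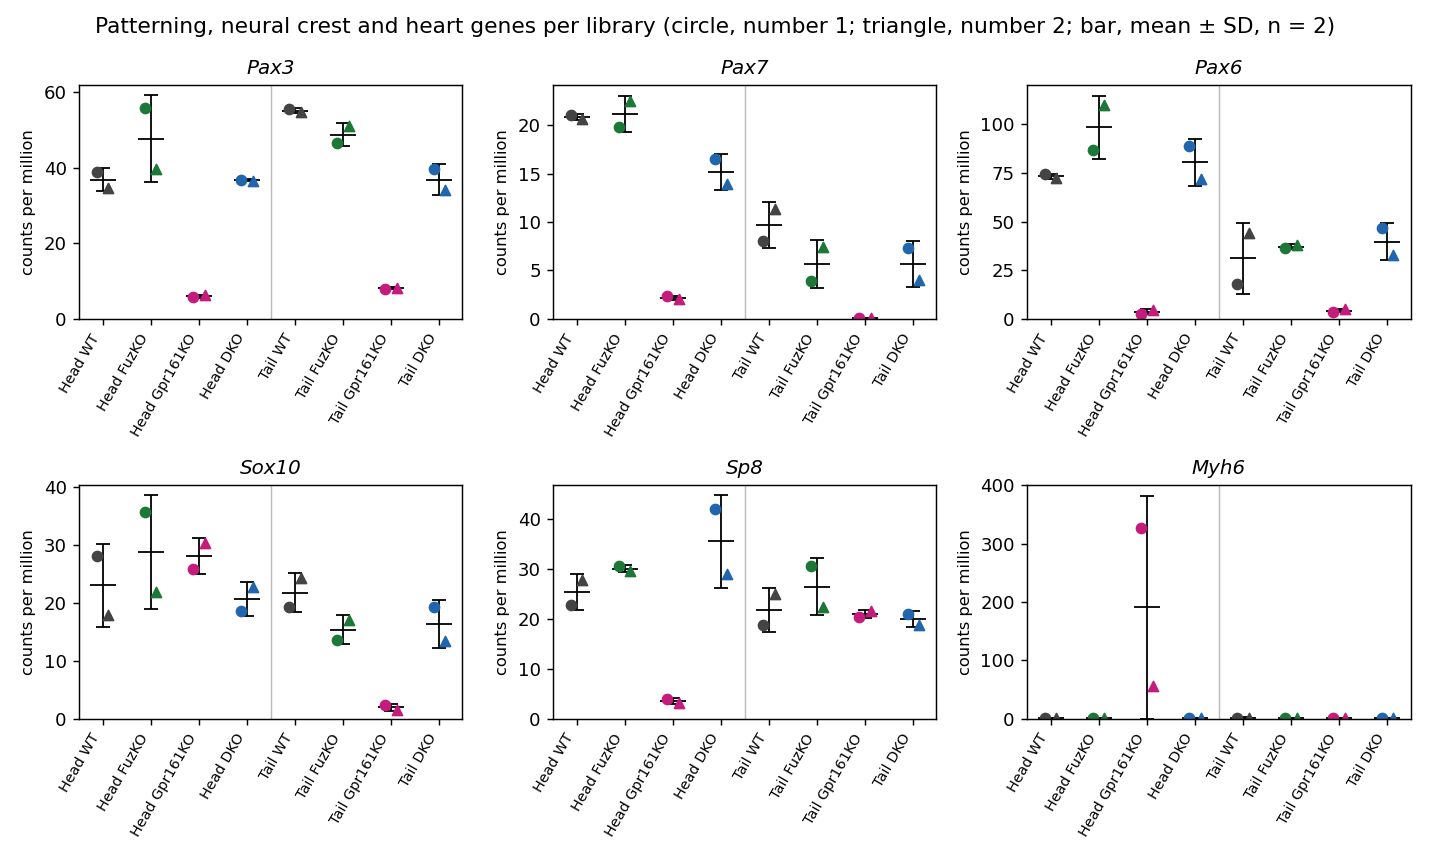
Expression of 6 genes (Pax3, Pax7, Pax6, Sox10, Sp8 and Myh6) in CPM, with symbols as for Gli1 above and bars for the mean ± SD (n = 2). Pax3 averaged 5.99 CPM in Head Gpr161 KO and 8.05 in Tail Gpr161 KO, below 36.8 and 55.1 in the WT of these regions.

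The Head of the DKO tests what loss of both genes does. Gpr161 fell from 54.5 ± 0.693 to 4.46 ± 1.38 CPM (SD, n = 2; log2 -3.61 ± 0.38, adjusted p = 0.00214), while Fuz was at log2 -2.23 ± 0.38 and did not pass (adjusted p = 0.0942). Foxl1, a forkhead gene that answers Hedgehog signals in mesenchyme, fell from 6.73 ± 1.62 to 0.661 ± 0.131 CPM (log2 -3.34 ± 0.42, adjusted p = 0.00972). Gli1 (22.6 ± 3.23 CPM, log2 -0.83 ± 0.18, adjusted p = 0.414), Ptch1 (log2 0.10 ± 0.26, adjusted p = 0.976), Hhip (log2 -0.37) and Shh (log2 -2.02 ± 0.32, adjusted p = 0.0708) did not pass. In the Hedgehog target list, 0 of 16 members rose and 1 fell, and 1 rose and 7 fell adjusted over the list alone (median log2 -0.92, camera adjusted p = 1.18e-07, adjusted p = 0.235 with an estimated correlation). The forebrain and eye genes lay lower (median log2 -0.77, camera adjusted p = 4.41e-09, adjusted p = 0.235 with an estimated correlation), at -0.64 in DKO 1 and -1.26 in DKO 2, where 0 of 31 members passed by edgeR, 10 did at an unadjusted p under 0.05 and 6 by DESeq2, while 0 rose and 7 fell adjusted over the list alone. FGF target genes lay higher (median log2 0.39, camera adjusted p = 1.79e-06, adjusted p = 0.235 with an estimated correlation), where 0 of 13 members passed by edgeR, 6 did at an unadjusted p under 0.05 and 1 by DESeq2, while 3 rose and 0 fell adjusted over the list alone. In the ventral neural tube list 0 of 26 members passed by edgeR, 6 did at an unadjusted p under 0.05 and 3 by DESeq2, while 0 rose and 5 fell adjusted over the list alone (median log2 -0.48, camera adjusted p = 5.96e-05, adjusted p = 0.58 with an estimated correlation). Of the CPLANE and intraflagellar transport genes, 0 of 40 members passed by edgeR, 0 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.342). The hypoxia and glycolysis genes were higher (median log2 1.69, camera adjusted p = 1.13e-08, adjusted p = 0.652 with an estimated correlation), with 2.33 in DKO 1 and 0.50 in DKO 2. Cardiomyocyte genes (median log2 0.40, camera adjusted p = 0.335, adjusted p = 0.876 with an estimated correlation) were not called, with adjusted p of 0.0464 without Head WT 2 and 0.0403 without Head DKO 2.

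Altogether 7 genes passed in Head DKO (1 higher, 6 lower, with 922 at an unadjusted p under 0.05). The pseudogenes Atp6v0c-ps2 (log2 -4.32 ± 0.41) and Rpl34-ps1 (log2 -3.95 ± 0.26, adjusted p = 2.04e-05) fell. Chosen after their values were seen, Gm9825 and the class I histocompatibility gene H2-Bl, annotated as a polymorphic pseudogene, fell, with 0.957 ± 0.153 and 0.46 ± 0.115 CPM against 19.6 ± 0.397 and 2.79 ± 0.235 in WT, and Gm11942 rose to 9.36 ± 0.821 CPM. The count was 4 without Head DKO 1. Of the 4 named genes called, 2 stayed called in every leave-one-out run, Atp6v0c-ps2 and Rpl34-ps1. Gpr161 had an adjusted p of 0.113 without Head DKO 1, and Foxl1 of 0.0832, 0.192 and 0.374 without Head WT 1, Head DKO 1 and Head DKO 2. Without both Fuz KO 1 libraries Fuz, Gli1 and Shh passed, with adjusted p of 0.0146, 0.0366 and 0.00233. With the block Fuz and Shh passed (adjusted p = 0.00743 and 0.00109), and by DESeq2 Fuz, Shh and Gli1 did (1.26e-06, 3.04e-07 and 0.0192). With sex as a term Gpr161 (log2 -3.73 ± 0.53, adjusted p = 0.0522) had a larger fold and a larger SE, and Foxl1 (log2 -2.47 ± 0.43, adjusted p = 0.157) a smaller fold. Without both Fuz KO 1 and both DKO 1 libraries Foxl1 (log2 -3.59 ± 0.64, adjusted p = 0.329) and Atp6v0c-ps2 (log2 -4.28 ± 0.70, adjusted p = 0.249) did not pass.

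The Tail of Fuz KO addressed the same question in the posterior embryo. Gli1 was at 24.2 ± 5.88 CPM against 42 ± 5.45 in WT (SD, n = 2; log2 -0.80 ± 0.18, adjusted p = 0.763), and Shh at 7.87 ± 1.02 against 16.4 ± 4.17 CPM (log2 -1.06 ± 0.32, adjusted p = 0.816). Fuz was at log2 -2.30 ± 0.39 (adjusted p = 0.241), Ptch1 at log2 -0.17 ± 0.26 and Gpr161 at log2 -0.55 ± 0.34, and none of these passed by edgeR. Fuz had an adjusted p of 0.0133 with the block and 8.99e-06 by DESeq2. Of the Hedgehog target genes, 0 of 16 members passed by edgeR, 8 did at an unadjusted p under 0.05 and 4 by DESeq2, while 0 rose and 7 fell adjusted over the list alone (median log2 -0.94, camera adjusted p = 1.07e-07, adjusted p = 0.382 with an estimated correlation). The dorsal neural tube list lay lower (median log2 -0.77, camera adjusted p = 2.06e-05, adjusted p = 0.425 with an estimated correlation), where 0 of 29 members passed by edgeR, 3 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone. The muscle lineage genes of the dermomyotome (median log2 -0.77, camera adjusted p = 3.12e-06, adjusted p = 0.465 with an estimated correlation) and the neuronal differentiation genes (median log2 -1.08, camera adjusted p = 1.41e-06, adjusted p = 0.607 with an estimated correlation) lay lower too. In the former 0 of 23 members passed by edgeR, 3 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone. In the latter 0 of 26 members passed by edgeR, 1 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone. In Fuz KO 1 and Fuz KO 2 the medians were -1.27 and -0.21 for the dorsal neural tube, -2.06 and -0.18 for the dermomyotome, and -1.86 and -0.17 for neuronal differentiation. Of the CPLANE and intraflagellar transport genes, 0 of 40 members passed by edgeR, 1 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.182). The hypoxia and glycolysis genes were higher (mean log2 1.71, camera adjusted p = 1.46e-06, adjusted p = 0.638 with an estimated correlation), with 2.27 in Fuz KO 1 and 0.10 in Fuz KO 2. Without Tail Fuz KO 1 the adjusted p was 0.859 for this list, 0.467 for neuronal differentiation and 0.295 for the dermomyotome, and without Tail WT 2 it was 0.857 for neuronal differentiation. With both Fuz KO 1 libraries left out it was 0.0533 for the dorsal neural tube.

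The genes called in Tail Fuz KO were 2 gene models, chosen after their values were seen, and 1109 genes had an unadjusted p under 0.05. Gm11942 rose to 11 ± 5.24 from 0.492 ± 0.0489 CPM and Gm6969 to 15.4 ± 2.95 from 0.268 ± 0.041 CPM. The count was 1 without Tail WT 1, 1 without Tail WT 2 and 4 without Tail Fuz KO 2.

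Tail Gpr161 KO was compared with Tail WT in the same way. Gli1 rose from 42 ± 5.45 to 122 ± 11.5 CPM (SD, n = 2; log2 1.54 ± 0.18, adjusted p = 0.00325), and Ptch1 from 145 ± 10.4 to 538 ± 8.92 CPM (log2 1.89 ± 0.26, adjusted p = 0.0129). Hhip (log2 2.04 ± 0.34), Foxa2 (log2 2.92 ± 0.37) and Foxf2 (log2 2.01 ± 0.33) rose with them. The hyaluronan synthase gene Has2 (log2 1.63 ± 0.26) and the hyaluronan link protein gene Hapln3 (log2 1.82 ± 0.27) rose. Among the Hedgehog targets, 7 of 16 members rose and 0 fell, and 12 rose and 0 fell adjusted over the list alone (median log2 1.75, camera adjusted p = 8.25e-23, adjusted p = 0.0085 with an estimated correlation). Shh was at log2 1.12 ± 0.31 and did not pass (adjusted p = 0.274). The co-receptor genes Cdon (log2 -1.34 ± 0.18) and Gas1 (log2 -1.23 ± 0.16) fell, and Gpr161 fell (log2 -3.44 ± 0.38, adjusted p = 0.00242), while Fuz was at log2 0.20 ± 0.36 (adjusted p = 0.997). Of the ventral neural tube genes, 2 of 26 members rose and 0 fell, and 7 rose and 3 fell adjusted over the list alone (median log2 0.41, camera adjusted p = 0.00233, adjusted p = 0.486 with an estimated correlation), with Ferd3l at log2 3.29 ± 0.52. That call was lost without Tail WT 1, at an adjusted p of 0.836. In the sclerotome and cartilage list 0 of 22 members passed by edgeR, 8 did at an unadjusted p under 0.05 and 5 by DESeq2, while 7 rose and 1 fell adjusted over the list alone (median log2 0.35, camera adjusted p = 6.41e-05, adjusted p = 0.125 with an estimated correlation).

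Neural tube and muscle genes changed in Tail Gpr161 KO as well. Pax3 fell from 55.1 ± 0.613 to 8.05 ± 0.262 CPM (n = 2; log2 -2.77 ± 0.17, adjusted p = 4.32e-06), Pax7 from 9.69 ± 2.37 to 0.0732 ± 0.0305 CPM (log2 -6.98 ± 0.50) and Msx3 from 16.1 ± 2.71 to 0.405 ± 0.304 CPM (log2 -5.32 ± 0.47). Atoh1, which specifies dorsal interneurons, was at 0 counts against 3.16 ± 1.36 CPM in WT. Of the dorsal neural tube genes, 0 of 29 members rose and 7 fell, and 0 rose and 25 fell adjusted over the list alone (median log2 -2.67, camera adjusted p = 1.03e-36, adjusted p = 0.0085 with an estimated correlation), with a median of -2.51 when genes at 0 are placed at their bound. The intermediate neural tube genes Prdm12 (log2 -3.60 ± 0.59), Prdm13 (log2 -6.54 ± 0.88), Dbx2 (log2 -5.68 ± 0.98) and Pax6 (log2 -2.87 ± 0.39) fell. In that list 0 of 11 members rose and 5 fell, and 0 rose and 8 fell adjusted over the list alone (median log2 -2.79, camera adjusted p = 2.22e-16, adjusted p = 0.0155 with an estimated correlation). Sox10 (log2 -3.49 ± 0.34) and Foxd3 (log2 -1.98 ± 0.33), which mark migrating neural crest, fell. The muscle lineage genes Cdh15 (log2 -4.16 ± 0.68), the dermomyotome gene Dmrt2 (log2 -3.65 ± 0.43) and Atp2a1, a calcium pump of muscle (log2 -4.24 ± 0.71), fell as well. In the dermomyotome list 0 of 23 members rose and 4 fell, and 0 rose and 14 fell adjusted over the list alone (median log2 -2.58, camera adjusted p = 6.73e-23, adjusted p = 0.0305 with an estimated correlation). The sensory placode and muscle gene Eya2 (log2 -1.73 ± 0.28) and Crabp2 (log2 -1.09 ± 0.18) fell. Cardiomyocyte genes lay lower (median log2 -1.36, camera adjusted p = 0.000452, adjusted p = 0.541 with an estimated correlation), at -1.55 in Gpr161 KO 1 and -0.86 in Gpr161 KO 2, where 0 of 20 members passed by edgeR, 8 did at an unadjusted p under 0.05 and 4 by DESeq2, while 1 rose and 3 fell adjusted over the list alone.

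The 65 genes that passed in Tail Gpr161 KO were 17 higher and 48 lower. The count was 41 without Tail WT 1, 25 without Tail WT 2, 15 without Tail Gpr161 KO 1 and 11 without Tail Gpr161 KO 2. Of the 29 named genes called, 7 stayed called in every leave-one-out run, among them Pax3, Pax7, Msx3, Sox10 and Foxa2. Gli1 and Gpr161 had adjusted p of 0.0511 and 0.073 without Tail Gpr161 KO 2, and Ptch1 of 0.11, 0.0959, 0.0981 and 0.0957 without Tail WT 1, Tail WT 2, Tail Gpr161 KO 1 and Tail Gpr161 KO 2. In the same order it was 0.184, 0.212, 0.0502 and 0.196 for Hhip and 0.118, 0.278, 0.0917 and 0.197 for Foxf2, which had 0.127 without both Fuz KO 1 and both DKO 1 libraries. Shh had an adjusted p of 0.0246 without both Fuz KO 1 libraries, 0.0246 with the block and 0.0317 by DESeq2. Of the 29 named genes, 19 passed with sex as a term.

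In the Tail of the DKO, Gpr161 fell from 49.1 ± 3.3 to 2.71 ± 0.824 CPM (SD, n = 2; log2 -4.18 ± 0.39, adjusted p = 0.000604), and Fuz was at log2 -2.16 ± 0.39 (adjusted p = 0.13). Gli1 was at 37.7 ± 3.25 CPM (log2 -0.16 ± 0.18, adjusted p = 0.901), Ptch1 at 159.9 ± 34.2 CPM (log2 0.14 ± 0.26), Hhip at log2 0.84 ± 0.33 and Shh at log2 -1.27 ± 0.32, and none of these passed by edgeR. The planar cell polarity gene Celsr1 fell from 73.6 ± 12.8 to 37.3 ± 7.38 CPM (log2 -0.98 ± 0.15, adjusted p = 0.0418). In the planar cell polarity list 0 of 24 members rose and 1 fell, and 0 rose and 2 fell adjusted over the list alone (median log2 -0.22, camera adjusted p = 0.00088, adjusted p = 0.266 with an estimated correlation), and without Tail DKO 2 its adjusted p was 0.117. In the Hedgehog target list, 0 of 16 members passed by edgeR, 3 did at an unadjusted p under 0.05 and 1 by DESeq2, while 0 rose and 1 fell adjusted over the list alone (median log2 -0.29, camera adjusted p = 0.0986, adjusted p = 0.563 with an estimated correlation). That list was called without Tail WT 1 (adjusted p = 0.00832) and without Tail DKO 1 (adjusted p = 0.0143). The pathway component genes lay slightly lower (median log2 -0.22, camera adjusted p = 3.5e-06, adjusted p = 0.103 with an estimated correlation), where 0 of 28 members passed by edgeR, 9 did at an unadjusted p under 0.05 and 2 by DESeq2, while 0 rose and 2 fell adjusted over the list alone. The dorsal neural tube genes lay lower (median log2 -0.86, camera adjusted p = 2.8e-10, adjusted p = 0.14 with an estimated correlation), where 0 of 29 members passed by edgeR, 15 did at an unadjusted p under 0.05 and 2 by DESeq2, while 0 rose and 8 fell adjusted over the list alone. Of the CPLANE and intraflagellar transport genes, 0 of 40 members passed by edgeR, 2 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.594). The hypoxia and glycolysis genes were higher (median log2 1.12, camera adjusted p = 5.42e-05, adjusted p = 0.569 with an estimated correlation), with 1.73 in DKO 1 and 0.30 in DKO 2. The list's adjusted p was 0.272 without Tail DKO 1.

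In all, 9 genes passed in Tail DKO, 2 higher and 7 lower. The pseudogenes Atp6v0c-ps2 (log2 -5.13 ± 0.44) and Rpl34-ps1 (log2 -4.04 ± 0.25) fell, and Ftl1-ps1, annotated as protein coding, rose (log2 2.16 ± 0.33). Chosen after their values were seen, Gm9825 (0.917 ± 0.0881 against 21.1 ± 0.28 CPM) and H2-Bl (0.397 ± 0.0912 against 2.61 ± 0.0342) fell, and Gm11942 rose to 11.9 ± 0.581 CPM. The count was 5 without Tail WT 1 and 5 without Tail DKO 2. Of the 5 named genes called, 3 stayed called in every leave-one-out run, Gpr161, Atp6v0c-ps2 and Rpl34-ps1. Without both Fuz KO 1 libraries Fuz and Shh passed, with adjusted p of 0.021 and 0.0385. Both also passed with the block (0.01 and 0.0486) and by DESeq2 (1.17e-05 and 0.0179). Of the 5 named genes, 3 passed with sex as a term, while Celsr1 (log2 -0.96 ± 0.22, adjusted p = 0.599) and Ftl1-ps1 (log2 2.25 ± 0.47, adjusted p = 0.455) had folds within 1 SE of those above and larger SE.

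Mutants were then compared with each other, to ask whether the DKO differs from each single mutant. In the Head, DKO and Fuz KO differed in 6 genes (1 higher in DKO, 5 lower). Gpr161 was lower in DKO (log2 -3.12 ± 0.37, adjusted p = 0.00826), as were Rpl34-ps1 (log2 -4.39 ± 0.26) and Atp6v0c-ps2 (log2 -4.03 ± 0.41). Gli1 was at log2 0.77 ± 0.19 (adjusted p = 1) and Ptch1 at log2 0.45 ± 0.26, which did not pass. Of the Hedgehog target genes, 0 of 16 members passed by edgeR, 4 did at an unadjusted p under 0.05 and 0 by DESeq2, while 1 rose and 0 fell adjusted over the list alone (median log2 0.32, camera adjusted p = 0.0395, adjusted p = 0.955 with an estimated correlation). The list's adjusted p was 0.935 without Head Fuz KO 2 and 0.177 without Head DKO 1. The count was 421 without Head Fuz KO 2, 3 without Head DKO 1 and 3 without Head DKO 2. Of the 3 named genes called, 1 stayed called in every leave-one-out run, Rpl34-ps1.

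Head DKO was also set against Head Gpr161 KO. Gli1 was at 22.6 ± 3.23 CPM in DKO and 84.6 ± 6.08 in Gpr161 KO (SD, n = 2; log2 -1.91 ± 0.19, adjusted p = 0.00014). Ptch1 (log2 -1.60 ± 0.26), Hhip (log2 -2.54 ± 0.34), Shh (log2 -4.16 ± 0.35), Foxa2 (log2 -5.70 ± 0.43) and Foxl1 (log2 -5.92 ± 0.46) were lower in DKO, as was Fuz (log2 -2.47 ± 0.39). Pax3 (36.6 ± 0.28 CPM, log2 2.61 ± 0.17), Pax7 (log2 2.80 ± 0.35), Pax6 (log2 4.43 ± 0.42), Sp8 (log2 3.34 ± 0.24), the neural progenitor gene Hes3 (log2 4.91 ± 0.78) and Fgf8, the midbrain organiser ligand (log2 2.12 ± 0.32), were higher. Myh6 was lower (log2 -7.71 ± 0.88). Among the Hedgehog targets, 0 of 16 members rose and 11 fell, and 1 rose and 13 fell adjusted over the list alone (median log2 -2.57, camera adjusted p = 1.33e-15, adjusted p = 0.0568 with an estimated correlation). Of the dorsal neural tube genes, 9 of 29 members rose and 0 fell, and 17 rose and 1 fell adjusted over the list alone (median log2 1.48, camera adjusted p = 2.15e-12, adjusted p = 0.122 with an estimated correlation). In total 886 genes differed, 219 higher and 667 lower in DKO. The count was 327 without Head Gpr161 KO 1, 325 without Head Gpr161 KO 2, 211 without Head DKO 1 and 271 without Head DKO 2. Of the 53 named genes called, 28 stayed called in every leave-one-out run, among them Gli1, Hhip, Shh, Foxa2, Pax3 and Pax6.

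Head Fuz KO and Head Gpr161 KO differed in 1250 genes, 364 higher and 886 lower in Fuz KO. Gli1 (log2 -2.67 ± 0.19) and Ptch1 (log2 -2.05 ± 0.27) were lower in Fuz KO, and Pax3 (log2 2.99 ± 0.17) was higher. Among Hedgehog target genes 0 of 16 members rose and 10 fell, and 0 rose and 13 fell adjusted over the list alone (median log2 -3.03, camera adjusted p = 9.74e-16, adjusted p = 0.0553 with an estimated correlation). The count was 581 without Head Fuz KO 1, 3442 without Head Fuz KO 2, 460 without Head Gpr161 KO 1 and 474 without Head Gpr161 KO 2. Of the 61 named genes called, 44 stayed called in every leave-one-out run, among them Gli1, Ptch1 and Pax3.

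In the Tail, DKO and Fuz KO differed in 7 genes, 0 higher and 7 lower in DKO. Gpr161 (log2 -3.62 ± 0.38), Celsr1 (37.3 ± 7.38 against 75 ± 6.93 CPM, log2 -1.01 ± 0.15, adjusted p = 0.0408), Atp6v0c-ps2 and Rpl34-ps1 were lower. Gli1 was at log2 0.64 ± 0.18 (adjusted p = 1). Canonical Wnt targets lay lower in DKO (median log2 -0.37, camera adjusted p = 1.71e-06, adjusted p = 0.0184 with an estimated correlation), where 0 of 19 members passed by edgeR, 6 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 3 fell adjusted over the list alone. Of the tail bud and presomitic mesoderm genes, 0 of 23 members passed by edgeR, 15 did at an unadjusted p under 0.05 and 2 by DESeq2, while 0 rose and 8 fell adjusted over the list alone (median log2 -1.17, camera adjusted p = 6.62e-13, adjusted p = 0.16 with an estimated correlation). Their median lay at 1.10 in Fuz KO 1, -0.01 in Fuz KO 2, -0.38 in DKO 1 and -0.89 in DKO 2. The count was 4 without Tail DKO 2. Of the 4 named genes called, 2 stayed called in every leave-one-out run, Atp6v0c-ps2 and Rpl34-ps1.

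Tail DKO and Tail Gpr161 KO differed in 111 genes, with 32 higher and 79 lower in DKO. Gli1 (log2 -1.69 ± 0.19), Ptch1 (log2 -1.75 ± 0.26), Shh (log2 -2.38 ± 0.33) and Foxa2 (log2 -4.92 ± 0.42) were lower in DKO. Pax7 (5.65 ± 2.34 against 0.0732 ± 0.0305 CPM, log2 6.20 ± 0.49), Msx3 (log2 4.20 ± 0.46), Pax3 (log2 2.19 ± 0.16) and Sox10 (log2 3.07 ± 0.33) were higher, while Celsr1 (log2 -1.16 ± 0.15) and the polarity ligand Wnt5a (log2 -1.05 ± 0.16) were lower. In the Hedgehog target list, 0 of 16 members rose and 7 fell, and 0 rose and 13 fell adjusted over the list alone (median log2 -1.72, camera adjusted p = 3.18e-19, adjusted p = 0.0277 with an estimated correlation). The count was 25 without Tail Gpr161 KO 1, 19 without Tail Gpr161 KO 2, 17 without Tail DKO 1 and 13 without Tail DKO 2. Of the 29 named genes called, 8 stayed called in every leave-one-out run, among them Gli1, Foxa2, Pax3, Pax7 and Sox10.

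Tail Fuz KO and Tail Gpr161 KO differed in 84 genes, 36 higher and 48 lower in Fuz KO. Gli1 (log2 -2.34 ± 0.19) and Ptch1 (log2 -2.06 ± 0.27) were lower and Pax3 (log2 2.60 ± 0.17), Pax7 (log2 6.21 ± 0.49) and Sox10 (log2 2.98 ± 0.33) were higher in Fuz KO. Among Hedgehog target genes 0 of 16 members rose and 10 fell, and 0 rose and 14 fell adjusted over the list alone (median log2 -2.46, camera adjusted p = 6.04e-28, adjusted p = 0.00796 with an estimated correlation). The count was 31 without Tail Gpr161 KO 1 and 26 without Tail Gpr161 KO 2. Of the 25 named genes called, 13 stayed called in every leave-one-out run, among them Gli1, Ptch1, Pax3 and Sox10.

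Non-additivity asked whether the DKO departs from the sum of the single effects on the log2 scale, and positive values mean a DKO above that sum. In the Head, Pax6 (log2 4.01 ± 0.53), Sp8 (log2 3.09 ± 0.32), Msx1 (log2 2.12 ± 0.35), Gas1 (log2 1.74 ± 0.23) and Pax3 (log2 2.24 ± 0.22, adjusted p = 0.00099) lay above the sum. Pax6 averaged 73.2 CPM in WT, 98.3 in Fuz KO, 3.71 in Gpr161 KO and 80.3 in DKO. Foxa2 (log2 -3.98 ± 0.53) and the cardiac genes Myh6 (log2 -8.43 ± 1.24) and Actn2 (log2 -5.18 ± 0.86), which were high in Gpr161 KO 1, lay below it, with log2 -8.29 ± 1.35, adjusted p = 0.0514 and -5.16 ± 0.93, adjusted p = 0.0514 with the block. Gli1 (log2 -0.31 ± 0.26, adjusted p = 0.801) and Ptch1 (log2 -1.24 ± 0.36, adjusted p = 0.291) did not pass. Of the Hedgehog target genes, 0 of 16 members rose and 1 fell, and 0 rose and 6 fell adjusted over the list alone (median log2 -1.15, camera adjusted p = 4.57e-07, adjusted p = 0.136 with an estimated correlation). Of the dorsal neural tube genes, 3 of 29 members rose and 0 fell, and 15 rose and 0 fell adjusted over the list alone (median log2 1.51, camera adjusted p = 1.04e-15, adjusted p = 0.136 with an estimated correlation). A total of 35 genes passed, 13 above and 22 below the sum. The count was 11 without Head WT 1, 12 without Head WT 2, 20 without Head Fuz KO 1, 545 without Head Fuz KO 2, 21 without Head Gpr161 KO 1, 17 without Head DKO 1 and 11 without Head DKO 2. Of the 11 named genes called, 3 stayed called in every leave-one-out run, Pax3, Sp8 and Atp6v0c-ps2.

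In the Tail, 9 genes departed from the sum, 7 above and 2 below. Pax7 (log2 6.96 ± 0.60, adjusted p = 0.000353), Msx3 (log2 4.97 ± 0.58), Sox10 (log2 3.58 ± 0.44) and Pax3 (log2 2.37 ± 0.22) lay above it, and Atp6v0c-ps2 (log2 -5.65 ± 0.55) below. Pax3 averaged 55.1 CPM in WT, 48.8 in Fuz KO, 8.05 in Gpr161 KO and 36.8 in DKO. Gli1 (log2 -0.90 ± 0.26, adjusted p = 0.523) and Ptch1 (log2 -1.58 ± 0.36, adjusted p = 0.321) did not pass. Among the Hedgehog targets, 0 of 16 members passed by edgeR, 6 did at an unadjusted p under 0.05 and 2 by DESeq2, while 0 rose and 4 fell adjusted over the list alone (median log2 -0.84, camera adjusted p = 1.45e-07, adjusted p = 0.106 with an estimated correlation). Of the dorsal neural tube genes, 4 of 29 members rose and 0 fell, and 11 rose and 0 fell adjusted over the list alone (median log2 2.37, camera adjusted p = 1.97e-19, adjusted p = 0.0732 with an estimated correlation). The count was 105 without Tail Fuz KO 2. Of the 5 named genes called, 5 stayed called in every leave-one-out run, Pax7, Pax3, Msx3, Sox10 and Atp6v0c-ps2.

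Whether an effect differs by region was tested directly. For Fuz KO, 0 genes differed between Tail and Head by edgeR (452 at an unadjusted p under 0.05, 0 by DESeq2), with Gli1 at log2 0.79 ± 0.26 (adjusted p = 1). The count was 1 with the block, 70 with no filter on low counts and 19 without Head Fuz KO 2. For DKO, 0 genes differed by edgeR (692 at an unadjusted p under 0.05, 11 by DESeq2), with Gli1 at log2 0.67 ± 0.26, and the count was 19 with the block and 144 with no filter.

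For Gpr161 KO, 20 genes differed between regions, 4 higher and 16 lower in the Tail effect, and 217 did with the block, 16 of the 20 among them. Not among them were Myl4 (log2 -11.15 ± 1.34, adjusted p = 0.0602), Actn2 (log2 -6.21 ± 1.10, adjusted p = 0.113), Sox10 (log2 -3.81 ± 0.60, adjusted p = 0.0686) and Des (log2 -2.89 ± 0.57, adjusted p = 0.153). Sp8 (log2 2.79 ± 0.32, adjusted p = 0.00792) and the homeobox gene Evx1 (log2 5.18 ± 0.67) had a larger decrease in the Head or a rise in the Tail. Sox10 (log2 -3.78 ± 0.44, adjusted p = 0.00792), Foxd3 (log2 -3.05 ± 0.46), Pax7 (log2 -3.72 ± 0.62) and Sim1 (log2 -2.85 ± 0.45) had a lower log2 change in the Tail. Sox10 was at 23 CPM in Head WT and 28.1 in Gpr161 KO, against 21.8 and 1.93 in the Tail. The cardiac and muscle genes Myh6 (log2 -11.36 ± 1.29), Myl4 (log2 -11.25 ± 1.62), Actn2 (log2 -6.50 ± 0.87) and Des (log2 -2.99 ± 0.42) had a lower log2 change in the Tail, and they were high in the Head Gpr161 KO libraries, most in number 1. Of the cardiomyocyte genes, 0 of 20 members rose and 3 fell, and 0 rose and 18 fell adjusted over the list alone (median log2 -8.58, camera adjusted p = 1.49e-39, adjusted p = 0.0565 with an estimated correlation). In the dermomyotome list 0 of 23 members rose and 2 fell, and 0 rose and 15 fell adjusted over the list alone (median log2 -3.58, camera adjusted p = 3.94e-22, adjusted p = 0.0565 with an estimated correlation). Gli1 (log2 0.46 ± 0.26, adjusted p = 1) and Ptch1 (log2 0.19 ± 0.36) did not differ by the test. The count was 2 without Head WT 1, 0 without Head WT 2, 7 without Head Gpr161 KO 1, 50 without Head Gpr161 KO 2, 8 without Tail WT 1, 3 without Tail WT 2, 3 without Tail Gpr161 KO 1 and 3 without Tail Gpr161 KO 2. Of the 11 named genes called, 0 stayed called in every leave-one-out run.

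Head WT and Tail WT, compared to show how the regions differ, were different in 802 genes, 431 higher and 371 lower in the Head, and in 2007 with the block, 780 of the 802 among them. The head and forebrain genes Otx2 (60.4 ± 3.15 against 0.0457 ± 0.0647 CPM, log2 10.25 ± 0.85), Six3 (log2 8.78 ± 0.84) and Lhx8 (log2 8.43 ± 0.76) and the midbrain-hindbrain gene En2 (log2 6.49 ± 0.56) were higher in the Head. Nr2e1, Nkx2-1 and Six6 had 0 counts in Tail WT and 32.4 ± 3.17, 21.6 ± 0.543 and 9.14 ± 1.18 CPM in Head WT. Hoxa10 (log2 -10.11 ± 0.49), Hoxc8 (log2 -8.45 ± 0.46), the hindlimb gene Tbx4 (log2 -5.57 ± 0.30), the somite gene Meox1 (log2 -6.50 ± 0.31) and Aldh1a2 (log2 -5.42 ± 0.51) were lower in the Head, and Hoxc10 had 0 counts there and 60.4 ± 7.32 CPM in the Tail. Of the forebrain and eye genes, 20 of 31 members rose and 0 fell, and 24 rose and 0 fell adjusted over the list alone (camera adjusted p = 1.25e-27). Of the posterior Hox genes, 0 of 16 members rose and 16 fell, and 0 rose and 16 fell adjusted over the list alone, with a median of -8.85 at the bound (adjusted p = 0.00359 with an estimated correlation). Of the Hox genes of groups 1 to 8, 0 of 22 members rose and 18 fell, and 0 rose and 20 fell adjusted over the list alone, with a median of -7.47 at the bound (adjusted p = 0.00424 with an estimated correlation). Gli1 was at log2 -0.07 ± 0.18 and Gpr161 at log2 0.15 ± 0.34, which did not pass. The count was 308 without Head WT 1, 344 without Head WT 2 and 343 without Tail WT 1. Of the 56 named genes called, 36 stayed called in every leave-one-out run.

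Fold changes against WT were related between genotypes across 21279 genes, which are not independent replicates. The pairs within a region share their WT libraries, so r is positive by chance: over 20 simulations it was 0.495 in the Head and 0.503 in the Tail. Head Fuz KO and Head DKO had r = 0.559 (covariance 0.394, simulated 0.254), with 74.4% of genes of 1 sign (simulated 66.6%), and r was 0.724 with the stricter filter, 0.370 without Head Fuz KO 1 and 0.323 without Head DKO 1. Head Gpr161 KO and Head DKO had r = 0.375 (covariance 0.324), which was 0.612 without Head WT 1 and 0.602 without Head WT 2. Head Fuz KO and Head Gpr161 KO had r = 0.259 (covariance 0.225), and r was 0.494 without Head WT 1, 0.551 without Head WT 2, 0.150 without Head Fuz KO 1 and 0.166 without Head Gpr161 KO 1. In the Tail, r was 0.592 for Fuz KO and DKO (covariance 0.393, simulated 0.265), 0.461 for Gpr161 KO and DKO (covariance 0.347) and 0.447 for Fuz KO and Gpr161 KO (covariance 0.361, r = 0.280 without Tail Fuz KO 1). With 1 WT library for each mutant of a pair, both ways, no control was shared. Head Fuz KO and DKO then had r = 0.056 and 0.213, Head Gpr161 KO and DKO 0.038 and 0.013, and Head Fuz KO and Gpr161 KO -0.079 and 0.063. In the Tail r was 0.141 and 0.132, 0.075 and 0.063, and 0.075 and 0.079 for these pairs. With the stricter filter as well, Fuz KO and DKO had r = 0.447 and 0.490 in the Head and 0.316 and 0.348 in the Tail, and the other pairs 0.075 to 0.162. Between Head and Tail, which share no libraries, r was 0.317 for Fuz KO, 0.192 for Gpr161 KO and 0.194 for DKO. For Fuz KO it was 0.091 without Head Fuz KO 1 and 0.103 without Tail Fuz KO 1, and for Gpr161 KO 0.124 without Head WT 2. For DKO it was 0.083 without Head DKO 1, 0.107 without Tail WT 2 and 0.110 without Tail DKO 1. For Gpr161 KO, 14 genes rose in both regions (0.256 with independent calls), 18 fell in both (0.244) and 1 changed in opposite directions, and 353 of the 429 genes called in the Head had the same sign in the Tail.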

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

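All tests of explanations in this part were chosen after the results were seen, while the test of the Gpr161 KO effect between regions was planned.

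The Gpr161 KO effect differed between Tail and Head in 20 genes by the interaction test, with the log2 difference given as Tail minus Head. Evx1 (5.18) and Sp8 (2.79) had a higher log2 change in the Tail, that is, a less negative or more positive one than in the Head. Sim1 (-2.85), Pax7 (-3.72), Sox10 (-3.78) and Foxd3 (-3.05), genes of neurons, dorsal neural tube and neural crest, had a lower log2 change there, that is, a more negative or less positive one. Myh6 (-11.36), Myl4 (-11.25), Asb2 (-6.86), Actn2 (-6.50) and Des (-2.99), genes of heart and striated muscle, also had a lower log2 change in the Tail, and Myh6 was at 326 and 55.9 CPM in the Head Gpr161 KO libraries against 0.4 in Head WT. With Head and Tail libraries paired by genotype and number as a block, the count was 217, of which 16 were among the 20. Sox10, Myl4, Actn2 and Des were not. Of the 11 named genes called, 0 stayed called in every leave-one-out run.

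Cardiomyocyte genes were high in Head Gpr161 KO and differed between its libraries, with a median of 4.52 times more in number 1 over 15 genes. If heart tissue was carried into these libraries, its genes should keep 1 ratio, but the SD of their log2 ratios, 0.495 around a median of 2.18, was near that of the Hedgehog targets (0.488) and decides nothing. The targets did not move with heart genes (median -0.22, lower by 2.39), but 1 pair of libraries decides no cause. In these libraries Hox genes 1 to 8 (0.67, 1.12) and gut genes (1.08, 0.715) lay above WT. How much heart a Head holds is not given in the sources, so carried-over heart and a moved heart stay open.

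Hypoxia and glycolysis genes were higher in number 1 of each mutant genotype than in number 2, in both regions. Depth was argued against, since the totals of a mutant pair differed by at most 1.2 times. The number 2 median was at most 0.432 of that of number 1, and Spearman's rho over the 8 pairs of Head and Tail libraries of 1 genotype and number was 0.976. Both values restate the pattern and decide nothing. A state shared by libraries of 1 number, such as handling or the condition of an embryo, and a genotype effect stay open and untested.

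Genes annotated as pseudogenes, with H2-Bl and without Ftl1-ps1, made up 6 of the 18 genes called in Fuz KO or DKO against WT (33.3%), against 6.78% of the genes tested (Fisher's exact p = 0.000874). Sequence variants carried by the embryos of a group could give such calls and stay open, as do reads shared with a parent gene. Reads moving from Rpl34-ps1 and Atp6v0c-ps2 to their parent genes would need the parent to gain what the pseudogene lost, and the gain was at least 1.347 times the loss in 6 pseudogene and comparison pairs, 2 of them in Gpr161 KO, and up to 7.17 times for Rpl34. Ftl1-ps1 rose by 4.77 CPM in Tail DKO while its parent Ftl1 rose by 99.7 CPM, which is not the fall that reads moving to Ftl1-ps1 would give, but the SD of Ftl1 there (33.6) would hide it. An effect of losing Fuz that does not depend on Gpr161 was argued against for Gm6969, at log2 -6.74 in Head DKO against Head Fuz KO (edgeR adjusted p = 0.000543), and so was sex, since male libraries of 2 genotypes lay at least 2.01 apart on the log2 scale for each of the 6 pseudogenes in each region.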

How the results depend on the processing

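As listed above, 5 of the alternatives were chosen after the data were seen, and the others before. Every count of calls stayed within 1.5 times its value with RLE scaling, the stricter filter and no haemoglobin or mitochondrial genes. Removing 20 cardiomyocyte genes (Head Gpr161 KO, 429 to 416) could not pass that limit. The counts that moved further are given below by alternative, and the cause was not tested. Comparisons named by a genotype alone are against WT of the same region. With no filter on low counts the count was 780 for Head Fuz KO, 1319 for Head Gpr161 KO, 432 for Head DKO, 519 for Tail Fuz KO, 802 for Tail Gpr161 KO and 481 for Tail DKO. It also was 85 for Head DKO and Fuz KO, 1780 for Head DKO and Gpr161 KO, 2436 for Head Fuz KO and Gpr161 KO, 715 for Head non-additivity, 151 for Tail DKO and Fuz KO and 794 for Tail DKO and Gpr161 KO. Further values were 684 for Tail Fuz KO and Gpr161 KO, 549 for Tail non-additivity, 70 for the Fuz KO effect by region, 439 for the Gpr161 KO effect by region, 144 for the DKO effect by region and 1688 for Head WT and Tail WT. With each region fitted alone the count was 3 for Head Fuz KO, 258 for Head Gpr161 KO, 33 for Tail Gpr161 KO, 5 for Tail DKO, 575 for Head DKO and Gpr161 KO and 649 for Head Fuz KO and Gpr161 KO. It also was 17 for Head non-additivity, 59 for Tail DKO and Gpr161 KO and 4 for Tail non-additivity. With the replicate number as a block the count was 659 for Head Gpr161 KO, 14 for Head DKO, 4 for Tail Fuz KO, 122 for Tail Gpr161 KO, 19 for Tail DKO and 86 for Head non-additivity. It also was 231 for Tail DKO and Gpr161 KO and 127 for Tail Fuz KO and Gpr161 KO. Between regions, where the block was genotype and number together, it was 1 for the Fuz KO effect by region, 217 for the Gpr161 KO effect by region, 19 for the DKO effect by region and 2007 for Head WT and Tail WT. By DESeq2 the count was 49 for Head Fuz KO, 976 for Head Gpr161 KO, 57 for Head DKO, 24 for Tail Fuz KO, 319 for Tail Gpr161 KO and 144 for Tail DKO. It also was 12 for Head DKO and Fuz KO, 1805 for Head DKO and Gpr161 KO, 2455 for Head Fuz KO and Gpr161 KO, 316 for Head non-additivity, 25 for Tail DKO and Fuz KO and 718 for Tail DKO and Gpr161 KO. Further values were 345 for Tail Fuz KO and Gpr161 KO, 124 for Tail non-additivity, 227 for the Gpr161 KO effect by region, 11 for the DKO effect by region and 1413 for Head WT and Tail WT. Without both Fuz KO 1 libraries the count was 1039 for Head Gpr161 KO, 34 for Head DKO, 256 for Tail Gpr161 KO, 84 for Tail DKO, 10 for Head DKO and Fuz KO and 2120 for Head DKO and Gpr161 KO. It also was 896 for Tail DKO and Gpr161 KO, 176 for Tail Fuz KO and Gpr161 KO, 156 for the Gpr161 KO effect by region and 1360 for Head WT and Tail WT. Without both Fuz KO 1 and both DKO 1 libraries the count was 2211 for Head Gpr161 KO, 12 for Head DKO, 6 for Tail Fuz KO, 348 for Tail Gpr161 KO, 235 for Tail DKO and 2406 for Head DKO and Gpr161 KO. It also was 2086 for Head Fuz KO and Gpr161 KO, 65 for Head non-additivity, 1986 for Tail DKO and Gpr161 KO, 257 for Tail Fuz KO and Gpr161 KO, 17 for Tail non-additivity, 142 for the Gpr161 KO effect by region, 2 for the DKO effect by region and 1694 for Head WT and Tail WT. With sex as a term the count was 1 for Head Fuz KO, 196 for Head Gpr161 KO, 0 for Tail Fuz KO by edgeR (1109 at an unadjusted p under 0.05 without that term, 24 by DESeq2), 29 for Tail Gpr161 KO, 537 for Head DKO and Gpr161 KO and 702 for Head Fuz KO and Gpr161 KO. It also was 47 for Tail DKO and Gpr161 KO, 44 for Tail Fuz KO and Gpr161 KO and 43 for the Gpr161 KO effect by region. With each library left out in turn the count ran from 3 to 2256 for Head Fuz KO, from 42 to 189 for Head Gpr161 KO, from 4 to 6 for Head DKO, from 1 to 4 for Tail Fuz KO, from 11 to 41 for Tail Gpr161 KO and from 5 to 6 for Tail DKO. It ran from 3 to 421 for Head DKO and Fuz KO, from 211 to 327 for Head DKO and Gpr161 KO, from 460 to 3442 for Head Fuz KO and Gpr161 KO, from 11 to 545 for Head non-additivity, from 4 to 10 for Tail DKO and Fuz KO and from 13 to 25 for Tail DKO and Gpr161 KO. The range was from 26 to 106 for Tail Fuz KO and Gpr161 KO, from 7 to 105 for Tail non-additivity, from 0 to 19 for the Fuz KO effect by region, from 0 to 50 for the Gpr161 KO effect by region and from 308 to 644 for Head WT and Tail WT.

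No call of a named gene or reported list turned direction under the alternatives run. The named genes passed in 372 gene and comparison pairs, in 279 to 371 with a library left out and in 383 by DESeq2. Camera called 314 list tests, 16 with an estimated correlation, 105 by fry, and 285 to 328 with a library left out. Of the 58 calls among the 64 list results in the text, an estimated correlation ended 45, fry 27 and leaving out both Fuz KO 1 libraries 5, while RLE scaling and the block ended 0. RLE scaling moved the median log2 fold change by between -0.028 and 0.030. With the stricter filter, r between fold changes was 0.724 for Head Fuz KO and Head DKO, 0.610 for Head and Tail Fuz KO, 0.291 for Head and Tail Gpr161 KO and 0.518 for Head and Tail DKO. It was 0.691 for Tail Fuz KO and Tail DKO, and 0.278 for Head Gpr161 KO and Head DKO, 0.184 for Head Fuz KO and Head Gpr161 KO, 0.378 for Tail Gpr161 KO and Tail DKO and 0.409 for Tail Fuz KO and Tail Gpr161 KO. With the WT libraries split between a pair, so that no control was shared, the mean r was 0.134 for Head Fuz KO and DKO, 0.026 for Head Gpr161 KO and DKO, -0.008 for Head Fuz KO and Gpr161 KO, 0.137 for Tail Fuz KO and DKO, 0.069 for Tail Gpr161 KO and DKO and 0.077 for Tail Fuz KO and Gpr161 KO. Calls of named genes ended in 77 pairs with sex as a term, 55 without both Fuz KO 1 and both DKO 1 libraries, 24 without both Fuz KO 1 libraries and 9 with the block. Against Gpr161 KO with sex as a term, 48 of 53 named genes passed in Head DKO, 54 of 61 in Head Fuz KO, 18 of 29 in Tail DKO and 20 of 25 in Tail Fuz KO. Depth limits genes with few counts: in the simulated Head Gpr161 KO comparison 54.8% of genes above 5 CPM were recovered at a log2 change of 1, against 34% of all changed genes.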

Other observations

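The lists below were fixed beforehand, and their description was chosen after the values were seen. Cholesterol synthesis genes lay higher in Tail Gpr161 KO (median log2 0.60, camera adjusted p = 1.94e-14, adjusted p = 0.21 with an estimated correlation). There 0 of 22 members passed by edgeR, 16 did at an unadjusted p under 0.05 and 1 by DESeq2, while 14 rose and 0 fell adjusted over the list alone. It lay at 0.66 and 0.51 (Fuz KO 0.59 and 0.01, DKO 0.47 and 0.145). Genes of the primitive and definitive erythroid lineage lay lower in Head Fuz KO (median log2 -0.89, camera adjusted p = 2.63e-08, adjusted p = 0.562 with an estimated correlation). Of these, 0 of 22 members passed by edgeR, 8 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone. The list lay at -1.28 in Fuz KO 1 and -0.63 in Fuz KO 2. They lay lower in Head DKO too (median log2 -0.88, camera adjusted p = 2.21e-10, adjusted p = 0.58 with an estimated correlation), at -1.65 in DKO 1 and -0.36 in DKO 2, and 0 of 22 members passed by edgeR, 3 did at an unadjusted p under 0.05 and 0 by DESeq2, while 0 rose and 0 fell adjusted over the list alone. Tail bud and presomitic mesoderm genes lay below the sum of the single effects in Tail DKO (median log2 -2.38, camera adjusted p = 6.75e-13, adjusted p = 0.106 with an estimated correlation). Of this list, 0 of 23 members passed by edgeR, 12 did at an unadjusted p under 0.05 and 6 by DESeq2, while 0 rose and 11 fell adjusted over the list alone. It lay at 1.10 and -0.01 in the Tail Fuz KO libraries, 1.27 and 0.47 in Gpr161 KO and -0.38 and -0.89 in DKO.

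Genes of the unfolded protein and amino acid response had a median log2 difference from WT of 1.04 in Head Fuz KO 1, 1.05 in Head DKO 1, 1.11 in Tail Fuz KO 1 and 0.68 in Tail DKO 1. In number 2 of these groups, in the same order, it was -0.04, 0.17, 0.04 and 0.27. Mitochondrially encoded genes were at -1.16 and 0.03 in the Head Fuz KO libraries, -0.61 and -0.51 in Gpr161 KO and -0.67 and -0.02 in DKO. In the Tail they were at -0.99 and -0.01 in Fuz KO, -0.57 and -0.32 in Gpr161 KO and -0.59 and 0.14 in DKO.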
